A study of Caenorhabditis elegans with 8 samples.

How the data were processed

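RNA-seq read counts of whole Caenorhabditis elegans were analysed from a table that the authors deposited, with 8 libraries of total RNA extracted with TRIZOL, per the labels. The groups were control (3 libraries, DMSO), honokiol (2 libraries, 200 µM for 1 h) and magnolol (3 libraries, 200 µM for 1 h), and each library was placed by its title. The strain, stage and culture of each replicate are not given in the sources used here. The values are counts per gene as deposited by the authors, whole numbers without normalization. The submitters' processing notes name the genome build WBcel235 and DESeq2, with no role for either. The aligner, the counting tool, the annotation release, the strand setting and the treatment of reads that match several genes are not given in the sources used here, so overlapping and antisense genes cannot be told apart by strand.

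The table held 21309 rows, of which 20257 were gene models (1203 without a symbol) and 1052 were loci that the authors added. There were 404 symbols on more than 1 row, covering 869 rows, which are named with their row identifier where they are reported. Total counts were 33645839, 33041126 and 30274330 for controls 1 to 3, 34063355 and 31405321 for honokiol 1 and 2, and 33228081, 33939243 and 35888186 for magnolol 1 to 3. No pair of replicates was as close as counting noise, since chi-square per degree of freedom ran from 8.66 to 43.3 over the 7 pairs. Magnolol 2 stood apart from magnolol 1 and 3, at 43.3 and 33.8 against 8.66 between those 2, and control 3 from control 1 and 2, at 33.7 and 38.3 against 11.9. Between the honokiol libraries it was 30.8. Positions were taken from the WBcel235 annotation, Ensembl release 115, in which 96.9% of gene-model rows with a symbol were found once.

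Tests used edgeR 4.0.16 in R 4.3.3 on the counts as deposited. Genes were kept by filterByExpr by group with its defaults (16813 rows, 624 of them added loci), libraries were scaled by TMM, and a model of group means over all 8 libraries was fitted with glmQLFit. Magnolol against control, honokiol against control and magnolol against honokiol were then tested two-sided with glmQLFTest and Benjamini-Hochberg adjustment at 0.05. The biological coefficient of variation was 14.1%, with 5 residual and 9.35 prior degrees of freedom. CPM values were computed from TMM-scaled library sizes. At an unadjusted p under 0.05 there were 2593, 1822 and 2699 genes in these comparisons.

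Of 37 lists of genes (28 pathways and 9 groups of tissue or stage markers), those with at least 5 tested members were tested by camera from limma 3.58.1 with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists of a comparison. Each test was repeated with an estimated correlation, and counts of called members were also adjusted over the list alone. Some genes belong to several lists, so the list tests are not separate from each other. The lists, the tests, the alternatives and the rule for naming genes were fixed before the data were examined. The rule took, per comparison, the 10 largest rises and the 10 largest falls among called genes at or above the median level whose groups did not overlap. It also took up to 4 members with the smallest p of each list that camera called or that had at least 3 called members, and a fixed set of stress reporter genes called or not. Other genes are marked where they are named.

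The overlap of the responses was set beside 100 simulated draws of unchanged groups. In each draw all libraries, the controls included, were drawn around the mean of the controls, with each gene drawn independently. The test was first tested on simulated counts for 16388 genes. For magnolol against control it recovered 37.9%, 71.2% and 90.6% of genes changed by 1.5-fold, 2-fold and 4-fold, with 3.7% false calls. For honokiol against control it recovered 37.3%, 72.7% and 83.3% with 5.9% false calls, and between the isomers 42.7%, 75.6% and 89% with 3.9% false calls. Of 35 unchanged lists 0 were called by camera in the simulation of magnolol against control. These lists were random and their genes were simulated independently, so this is no check on lists whose members vary together.

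The alternatives were DESeq2 size factors, upper-quartile scaling, no low-count filter, a strict filter (50 counts in 3 libraries), DESeq2 1.42.0, limma-voom, a fit of only the groups compared, the replicate number as a block, 1 surrogate variable (sva 3.50.0), a threshold of 0.01, a 2-fold minimum and each library left out in turn. For the lists, fry from limma was an alternative to camera. Where leaving out a honokiol library left 1, that library was assumed to vary like the other groups. Chosen after the data were seen were a fit without the added loci, a fit with rows of a symbol summed, and a correction of each library for a trend with exon length. Plots were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.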

Results

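The deposited table held RNA-seq read counts from whole Caenorhabditis elegans, a nematode used as a laboratory model animal. Worms were exposed for 1 h to 200 µM of magnolol or honokiol, or to DMSO as the control. Both compounds are biphenols of Magnolia bark. They are positional isomers, carrying the same allyl and hydroxyl groups at different positions of the joined rings. There were 3 control libraries, 2 honokiol libraries and 3 magnolol libraries, with total counts per library of 30274330 to 35888186. The labels do not say that the replicates came from separate cultures, so the p-values measure the spread between these samples, which may be technical. Of 21309 rows in the table, 16813 passed the low-count filter and were tested. Levels are given in CPM (counts scaled to the size of each library) as mean ± SD, with n = 3 for control and magnolol and n = 2 for honokiol. Changes are log2 fold changes ± SE. A gene was called at an adjusted p under 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, two-sided.

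The first comparison asked which transcripts differed between worms given magnolol and worms given DMSO. Genes of the cytochrome P450, UDP-glucuronosyltransferase and cytosolic heat shock lists were higher with magnolol, in the numbers given for each list. The transcript of cyp-13A8, a cytochrome P450, stood at 130.3 ± 12.77 CPM with magnolol and 0.225 ± 0.292 CPM in control, a change of 9.10 ± 0.32. The transcript of pgp-1, a P-glycoprotein exporter of the ABC family, rose from 4.36 ± 0.339 to 808 ± 178 CPM, or 185-fold. The transcript of hsp-70, an inducible chaperone, rose from 1.05 ± 0.514 to 11.15 ± 0.972 CPM, or 10.7-fold. In all, 364 genes were called higher and 118 lower, 181 and 13 of them by at least 2-fold. The median change was 1.00 among the higher genes and -0.59 among the lower genes.

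The cytochrome P450s, which oxidise foreign and endogenous compounds, formed the group with the most calls. Of 73 tested members 29 rose, 2 fell and 42 were not called. Adjusted over the list alone, the counts were 36 higher and 6 lower. The list was called by camera with adjusted p = 1.24e-58, and with adjusted p = 0.00413 with an estimated correlation. Several members with large rises lie close together on chromosome II of WBcel235 as protein-coding genes, from cyp-13A4 (row gene7751, minus strand, 9795756 to 9797740) through cyp-13A5, cyp-13A6 and cyp-13A7 to cyp-13A8 (row gene7756, minus strand, 9805600 to 9807569). Besides cyp-13A8, their changes were 4.45 ± 0.14 for cyp-13A4, 5.54 ± 0.14 for cyp-13A5 and 6.62 ± 0.27 for cyp-13A7. A relative on chromosome III, cyp-13A12, rose from 2.23 ± 1.41 to 650.3 ± 63.5 CPM, by 8.17 ± 0.29. These genes are paralogs, and how reads shared between them were counted is not given in the sources used here, so their separate values are uncertain. The P450s that fell were cyp-37B1 (-0.56 ± 0.11) and cyp-37A1 (-0.37 ± 0.09), both named after their values were seen.

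Among UDP-glucuronosyltransferases, which attach sugar groups to small molecules, 22 of 66 rose and 44 were not called. Their list was called by camera with adjusted p = 1.00e-29, and with adjusted p = 0.00355 with an estimated correlation. Examples were ugt-37 (3.29 ± 0.15), ugt-19 (3.01 ± 0.10) and ugt-41 (1.87 ± 0.09). When adjusted over the list alone, 24 were higher and 4 lower. Of 45 glutathione S-transferases 9 rose, among them gst-44 (3.85 ± 0.22) and gst-33 (3.61 ± 0.13). Of 29 ABC exporters 8 rose, among them pgp-9 (2.05 ± 0.15), pgp-14 (1.03 ± 0.12) and mrp-2 (0.95 ± 0.11). No member of these 3 lists was called lower. Of the glutathione S-transferases 9 were higher and 2 lower when adjusted over the list alone, and 10 exporters were higher. The camera calls of the latter lists (2.02e-05 and 8.05e-11) were lost with the estimated value: adjusted p = 0.268 and 0.228 with an estimated correlation.

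Heat shock genes rose with magnolol. Of 15 rows in the cytosolic heat shock list 9 rose and 6 were not called, or 10 higher when adjusted over the list alone. The list was called by camera with adjusted p = 1.55e-37, and with adjusted p = 0.00474 with an estimated correlation. F44E5.4, of the HSP70 family, stands on 2 rows with nearly equal counts. Its row gene8423 went from 11.18 ± 9.72 to 239.9 ± 19.99 CPM. The control libraries were spread widely, at 7.30, 22.2 and 4.002 CPM. The small heat shock genes hsp-16.1 (2.74 ± 0.17 on row gene35931), hsp-16.48 (2.14 ± 0.15 on row gene35932) and hsp-16.41 (2.59 ± 0.32) rose too, the last named after its value was seen. Both hsp-16.1 and hsp-16.48 also stand on 2 rows, and these near-identical copies are uncertain as separate genes. Camera took each of the 15 rows, which hold 12 symbols, as a member, so its p-value with the preset correlation may be too small. The constitutive chaperones hsp-1 (0.35 ± 0.16) and hsp-90 (0.15 ± 0.10), added after their values were seen, were not called.

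Of 193 nuclear hormone receptor rows 17 rose and 0 fell, or 26 and 2 adjusted over the list alone. Examples were nhr-178 (3.99 ± 0.20), nhr-210 (3.21 ± 0.16) and nhr-237 (2.77 ± 0.18). Camera called this list with adjusted p = 0.00122, against adjusted p = 0.0782 with an estimated correlation. Of 15 stress transcription factors 9 rose (11 adjusted over the list alone), among them the bZIP gene zip-10 (1.39 ± 0.16), fos-1 (0.74 ± 0.12) and pqm-1 (0.58 ± 0.10). That camera call (adjusted p = 2.06e-09) became adjusted p = 0.133 with an estimated correlation. In the metal response list, cdr-1 (1.90 ± 0.18), cdr-4 (1.45 ± 0.10) and cdr-2 (1.33 ± 0.09), of a family first described for cadmium induction, rose and 1 of 17 rows fell (5 higher and 1 lower adjusted over the list alone). The lower gene was the ferritin gene ftn-1 (-0.64 ± 0.16), with adjusted p = 0.0405 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 0.0686 without control 2, 0.126 without control 3, and 0.0654, 0.168 and 0.118 without magnolol 1, 2 and 3. Its camera call (adjusted p = 0.00190) became adjusted p = 0.228 with an estimated correlation. Of 15 SKN-1 and oxidative stress targets 4 rose, the same count as adjusted over the list alone, including gst-5 (0.78 ± 0.12) and dhs-8 (2.97 ± 0.49), for which limma-voom gave adjusted p = 0.0738. This list had adjusted p = 0.0288 in camera, a call also lost without control 1, control 3, magnolol 1 or magnolol 3 (0.0557, 0.0550, 0.0777 and 0.0547), and adjusted p = 0.268 with an estimated correlation. The usual reporters of that response were not called: gst-4 was at -0.22 ± 0.12 and gcs-1 at 0.0047 ± 0.09. Nor were hsp-4 (0.11 ± 0.10), hsp-6 (0.34 ± 0.14), mtl-1 (-0.69 ± 0.30), cysl-2 (-0.23 ± 0.11), sod-3 (0.48 ± 0.25) and fmo-2 (-0.17 ± 0.28), which report other stress responses.

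Lower genes changed by smaller amounts. Among genes at or above the median level, those that fell included Y70C5A.3 (-0.98 ± 0.11 on row gene39222), F26G1.2 (-0.98 ± 0.15), cnp-3 (-0.95 ± 0.13), Y6G8.2 (-0.88 ± 0.12) and acs-7 (-0.81 ± 0.14), an acyl-CoA synthetase gene. The insulin-like peptide gene ins-33 fell by 1.37 on the log2 scale. Camera called neuropeptides (adjusted p = 0.00487) and sperm markers (adjusted p = 0.0183) lower and oocyte and eggshell markers (adjusted p = 0.0288) higher. With an estimated correlation these lists had adjusted p = 0.624, 0.432 and 0.665. The members called were 3 of 118, 1 of 51 and 0 of 12, or 5, 5 and 2 adjusted over the list alone. At an unadjusted p under 0.05, 5 of the oocyte markers were higher, with DESeq2 calling 2 and limma-voom 0. Without control 3, camera gave adjusted p = 0.0615 for the neuropeptides and 0.0615 for the sperm markers, and without magnolol 2 0.0543 for the sperm markers. For the oocyte markers camera gave 0.0548 without control 1, 0.0615 without control 3 and 0.109 without magnolol 2. Across uncalled genes the log2 changes rose with exon length (Spearman rho = 0.35 over 14389 genes, which are not independent replicates). After a correction for that trend, camera gave adjusted p = 0.625 for the neuropeptides and adjusted p = 0.652 for the sperm markers.

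The count of lower genes depended on single libraries: it was 64 without control 1, 64 without magnolol 1, 53 without magnolol 2 and 36 without magnolol 3, against 118 with all, and 236 in DESeq2.

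**Figure D1:**
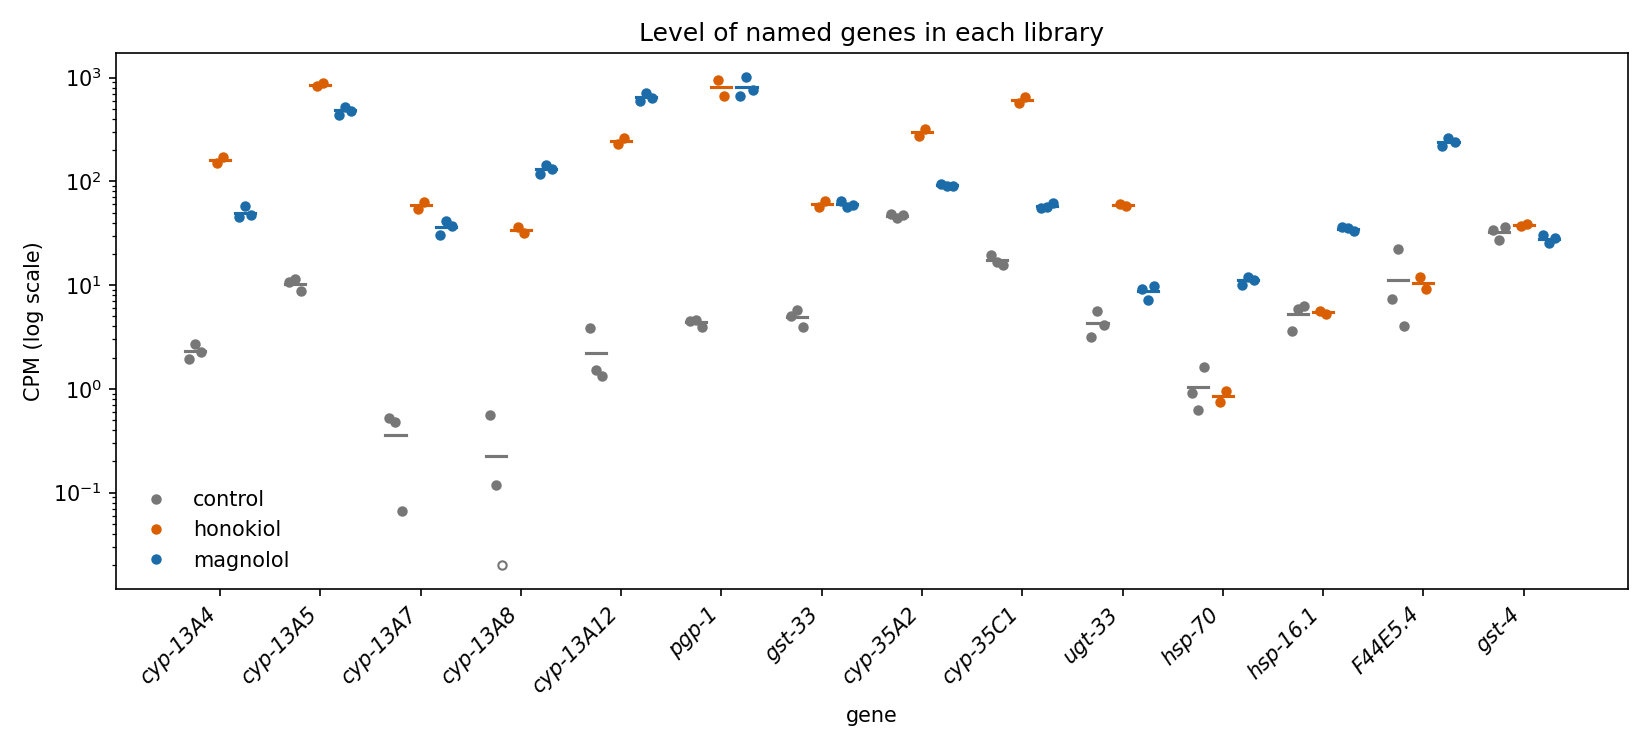
CPM of 14 named genes (horizontal axis) in each of the 8 libraries on a log scale (vertical axis), with points for libraries and bars for group means; the open point marks the control library with 0 counts of cyp-13A8, drawn at the bottom of the axis. The magnolol libraries lie above the honokiol libraries for cyp-13A8, cyp-13A12 and the heat shock genes and below them for cyp-35A2, cyp-35C1 and ugt-33, while both compounds raise pgp-1 to 808 and 804 CPM.

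The second comparison set honokiol against the same DMSO control. Genes of the P450 and UDP-glucuronosyltransferase families were higher with honokiol, the cyp-35 genes among them, and no member of the cytosolic heat shock list was called. The P450 gene cyp-35C1 rose from 17.3 ± 2.02 to 608 ± 59.8 CPM, by 5.13 ± 0.13. The exporter gene pgp-1 rose to 804 ± 202 CPM, or 184-fold. The short-chain dehydrogenase gene dhs-23 rose from 2.98 ± 0.160 to 78.7 ± 11.7 CPM. In all, 511 genes were called higher and 66 lower, 298 and 16 of them by at least 2-fold.

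Of the 73 P450s 37 rose, 1 fell and 35 were not called, or 45 and 3 adjusted over the list alone. The neighbours cyp-13A4 (6.13 ± 0.15), cyp-13A5 (6.36 ± 0.14), cyp-13A7 (7.31 ± 0.28) and cyp-13A8 (7.16 ± 0.33) all rose. On chromosome V, cyp-35A3 (3.87 ± 0.14) and cyp-35A2 (2.67 ± 0.10), a frequently used reporter of xenobiotic exposure, rose. Of the 66 UDP-glucuronosyltransferases 31 rose and 1 fell, or 39 and 3 adjusted over the list alone. Examples were ugt-37 (4.50 ± 0.16), ugt-19 (3.45 ± 0.11) and ugt-41 (3.19 ± 0.10). Camera called both lists, with adjusted p = 2.03e-114 and 2.87e-76, and with adjusted p = 0.00117 and 3.89e-04 with an estimated correlation. The members that fell were cyp-37B1 (-0.74 ± 0.13) and ugt-50 (-0.51 ± 0.12), the second named after its value was seen. Without honokiol 1, cyp-37B1 had adjusted p = 0.0914 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

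Nuclear hormone receptors, ligand-regulated transcription factors, rose in 36 of 193 rows, with 0 lower, or 55 higher and 2 lower adjusted over the list alone. Examples were nhr-178 (4.69 ± 0.21), nhr-237 (4.44 ± 0.18), nhr-232 (3.10 ± 0.16) and nhr-142 (2.87 ± 0.13). Metal response genes rose in 5 of 17 rows (6 higher and 1 lower adjusted over the list alone), among them cdr-1 (4.08 ± 0.18), cdr-4 (2.09 ± 0.10) and numr-2 (1.97 ± 0.20 on row gene11384, which shares its symbol with a near-identical copy). Camera called these lists with adjusted p = 2.47e-10 and 2.49e-12, and with adjusted p = 0.00847 and 0.0256 with an estimated correlation. Both rows of numr-2 had nearly equal CPM and do not count as separate genes. The metal reporter mtl-1 was at 2.404 and 4.243 CPM in honokiol 1 and 2, against 2.54, 3.51 and 4.895 CPM in controls 1 to 3. Of the glutathione S-transferases 10 of 45 rose, among them gst-44 (4.45 ± 0.23), gst-21 (4.10 ± 0.25) and gst-33 (3.62 ± 0.14), and of the ABC exporters 8 of 29 rose. Adjusted over the list alone, those counts were 16 and 9, with 1 lower in each list. Their camera calls (adjusted p = 1.25e-10 and 1.65e-06) became adjusted p = 0.151 and 0.317 with an estimated correlation. Of the SKN-1 and oxidative stress targets 4 of 15 rose, or 5 adjusted over the list alone, including gst-5 (2.25 ± 0.13) and gst-7 (1.01 ± 0.13), while the reporters gst-4 (0.22 ± 0.13) and gcs-1 (0.02 ± 0.10) were not called. That list went from adjusted p = 2.35e-05 in camera to adjusted p = 0.0877 with an estimated correlation.

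In the fat metabolism list 5 of 29 rose, among them the fatty acid elongase genes elo-2 (1.28 ± 0.11) and elo-6 (0.98 ± 0.12), the desaturase gene fat-5 (1.12 ± 0.13) and the lipid-binding protein gene lbp-8 (4.15 ± 0.58). Of 15 stress transcription factors 5 rose, among them zip-10 (1.46 ± 0.17), pqm-1 (1.12 ± 0.11) and the STAT gene sta-2 (0.86 ± 0.12). Of 25 innate immune effectors 4 rose, including irg-2 (1.41 ± 0.16) and lys-2 (0.74 ± 0.11), and of 30 short-chain dehydrogenases 4 rose, among them dhs-23 (4.72 ± 0.20). Adjusted over the list alone, those counts were 7, 9, 6 and 6. These 4 lists were called by camera with adjusted p = 0.00174, 3.73e-06, 0.0172 and 0.0407. With an estimated correlation they had adjusted p = 0.0877, 0.203, 0.357 and 0.516. Epidermis and molting markers were called lower by camera (adjusted p = 0.0172) with 1 of 20 members called (2 adjusted over the list alone), and had adjusted p = 0.398 with an estimated correlation. That member was mlt-10 (-0.51 ± 0.12), with adjusted p = 0.0224 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 0.0685 without control 3, 0.0722 without honokiol 1 and 0.221 without honokiol 2. Camera gave the short-chain dehydrogenases adjusted p = 0.0507 without control 2, 0.0959 without control 3 and 0.131 without honokiol 2. It gave the innate immune effectors 0.0716 without honokiol 2, and the epidermis and molting markers 0.0965 without control 3 and 0.168 without honokiol 2. After correction for a trend with exon length (Spearman rho = -0.19 over 14297 genes), camera gave adjusted p = 0.0660 for the short-chain dehydrogenases and called cuticle collagens lower at adjusted p = 0.0231.

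None of the 15 cytosolic heat shock rows was called with honokiol in edgeR, DESeq2 or limma-voom, and 0 had an unadjusted p under 0.05. The hsp-70 transcript was at 0.846 ± 0.147 CPM with honokiol, a change of -0.30 ± 0.35, and hsp-16.1 at 5.46 ± 0.253 CPM. Genes that fell included Y6G8.2 (-1.23 ± 0.13), T05F1.11 (-1.07 ± 0.19), R10E8.6 (-0.94 ± 0.15) and Y70C5A.3 (-0.82 ± 0.12). The osmotic reporter gpdh-1 rose with both compounds, by 0.50 ± 0.10 with magnolol and 0.52 ± 0.11 with honokiol. Its adjusted p in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was 0.0118 with honokiol and 0.156 without honokiol 1, and 0.0101 with magnolol and 0.0777 without magnolol 3. Leaving out control 2 gave 0.0509 for magnolol and 0.0515 for honokiol in that same edgeR test.

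With honokiol the count of lower genes was 36 without control 1, 39 without honokiol 1, 35 without honokiol 2 and 43 without magnolol 3, against 66 with all libraries. It was 116 in DESeq2.

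The third comparison set the isomers against each other at the same dose and time. Heat shock transcripts were higher with magnolol, and most P450, UDP-glucuronosyltransferase and metal response transcripts that differed were higher with honokiol. The hsp-70 transcript was at 11.15 ± 0.972 CPM with magnolol and 0.846 ± 0.147 CPM with honokiol, a difference of 3.71 ± 0.34, or 13.1-fold. The cyp-35C1 transcript was at 57.8 ± 3.22 CPM with magnolol and 608 ± 59.8 CPM with honokiol, or 10.5-fold higher with honokiol. Between the isomers 48 genes were called higher with magnolol and 209 higher with honokiol. The balance depended on the test and the libraries, with 302 and 301 in DESeq2 and 321 and 253 without honokiol 1.

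The cytosolic heat shock list had 8 of 15 rows called higher with magnolol and 7 not called, or 10 higher adjusted over the list alone. The differences were 4.51 ± 0.49 for F44E5.4 on row gene8423, 2.68 ± 0.20 for hsp-16.1 on row gene35931 and 2.06 ± 0.17 for hsp-16.48 on row gene35932. The list was called by camera with adjusted p = 8.34e-41, and with adjusted p = 0.00603 with an estimated correlation. The 15 rows hold 12 symbols, and the preset correlation of 0.01 takes rows of a symbol as nearly separate, so the first p-value may be too small. Outside the list, F19B2.5 (2.27 ± 0.14) and Y94H6A.10 (1.91 ± 0.12) were higher with magnolol.

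Of the 73 P450s 22 were higher with honokiol and 2 higher with magnolol, or 30 and 2 adjusted over the list alone. With magnolol minus honokiol as the difference, cyp-35A4 was at -4.04 ± 0.20, cyp-35A5 at -3.54 ± 0.16, cyp-35A3 at -2.79 ± 0.13 and cyp-35A2 at -1.70 ± 0.10. The neighbours cyp-13A4 (-1.68 ± 0.12), cyp-13A5 (-0.82 ± 0.12) and cyp-13A6 (-0.81 ± 0.19) were higher with honokiol, cyp-13A7 was not called (-0.70 ± 0.19), and the adjacent cyp-13A8 (1.94 ± 0.22) and the distant cyp-13A12 (1.40 ± 0.23) were higher with magnolol. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment cyp-13A8 and cyp-13A12 had adjusted p = 8.18e-05 and 0.00375. DESeq2 called neither, with adjusted p = 0.308 for cyp-13A8 and 0.0990 for cyp-13A12, at log2 differences of 1.95 and 1.41. Of the 66 UDP-glucuronosyltransferases 21 were higher with honokiol (32 adjusted over the list alone, with 2 higher with magnolol). Examples were ugt-33 (-2.76 ± 0.18) and ugt-9 (-2.52 ± 0.15). Camera called both lists, with adjusted p = 1.29e-35 and 4.48e-37, and with adjusted p = 0.00987 and 0.00199 with an estimated correlation.

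Other genes higher with honokiol included dhs-23 (-2.97 ± 0.18), E02C12.10 (-2.80 ± 0.16), the glucocerebrosidase homolog gba-2 (-2.14 ± 0.14), the carboxylesterase-family gene cest-33 (-1.77 ± 0.11) and gst-5 (-1.47 ± 0.13). In the metal response list 4 of 17 rows were higher with honokiol, with cdr-1 at -2.19 ± 0.16 and cdr-4 at -0.65 ± 0.10, and among nuclear hormone receptors 10 of 193 were higher with honokiol and 1, nhr-210 (1.04 ± 0.17), with magnolol. Those counts were 6, 28 and 1 adjusted over the list alone. Both lists were called by camera (adjusted p = 9.44e-09 and 1.22e-05), and had adjusted p = 0.0366 and 0.0236 with an estimated correlation. In the metal response list, rows gene11383 and gene11384 both carry the symbol numr-2. Their CPM was nearly equal, at 10.15 and 10.56 against 10.12 and 10.56 in the honokiol libraries. They do not count as separate genes. The epidermal peptide gene nlp-31, which is known as an infection and wound response gene, was at 29.7 ± 3.04 CPM with honokiol and 14.2 ± 0.389 CPM with magnolol, a difference of -1.06 ± 0.14. Elongase genes elo-2 (-0.87 ± 0.11) and elo-6 (-0.78 ± 0.12) were higher with honokiol.

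For several responsive genes no difference between the isomers was called. The 95% confidence interval of the log2 difference was -0.36 to 0.37 for pgp-1, -0.28 to 0.26 for gst-33, -0.20 to 0.22 for cdr-2, -0.39 to 0.16 for pgp-14, -0.37 to 0.16 for mrp-2 and -0.43 to 0.29 for zip-10. For the reporters gcs-1, hsp-4 and gst-4 it was -0.23 to 0.19, -0.18 to 0.30 and -0.72 to -0.16, so that the interval of gst-4 excluded 0 although its adjusted p in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was 0.119.

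**Figure D2:**
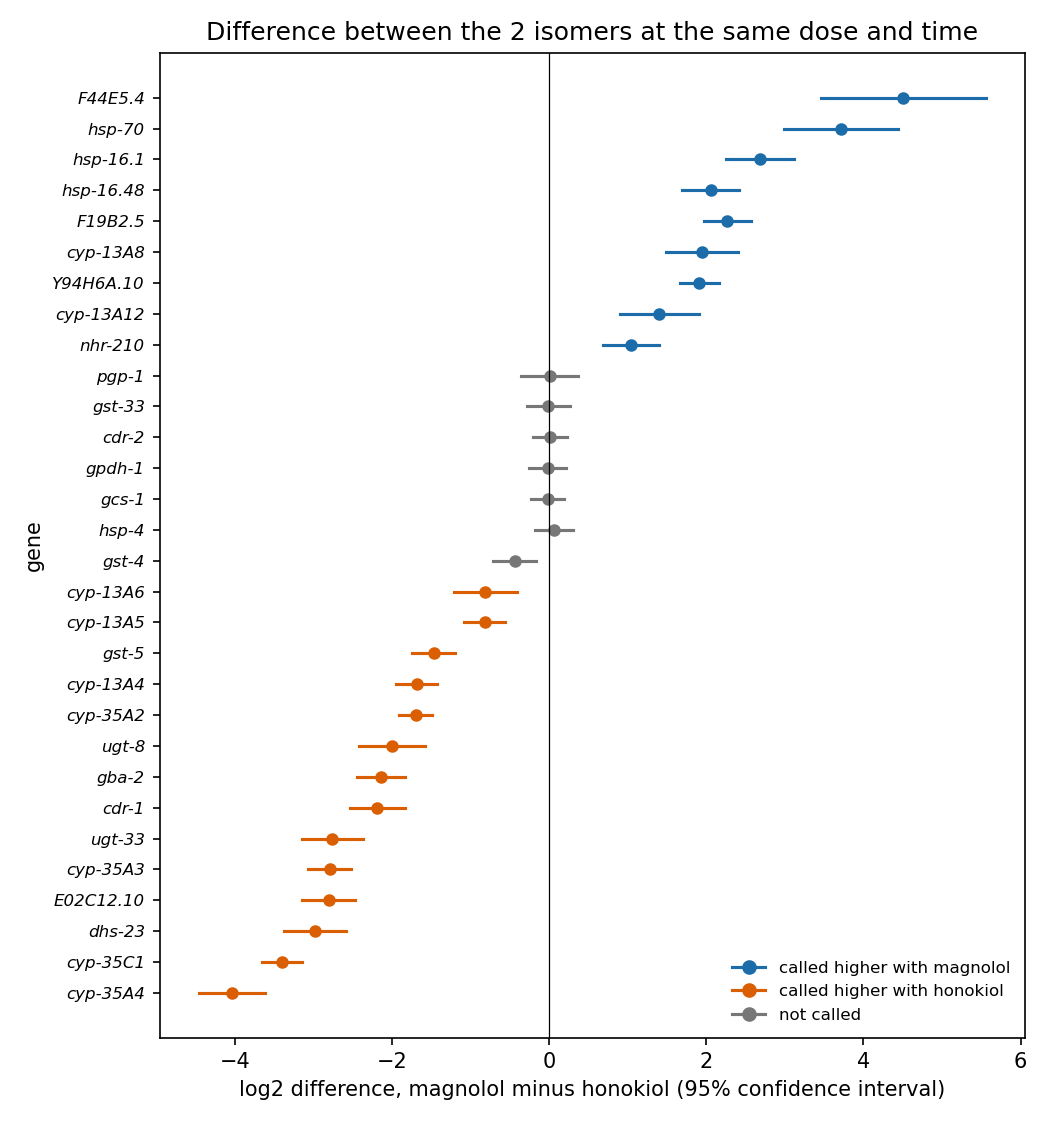
Log2 difference between magnolol and honokiol (horizontal axis) for 30 named genes (vertical axis), with the point for the estimate and the bar for its 95% confidence interval. The differences run from 4.51 for F44E5.4 to -4.04 for cyp-35A4, with pgp-1 at 0.01; DESeq2 did not call cyp-13A8 and cyp-13A12.

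Camera also called the following lists between the isomers, and each of these calls was lost with an estimated correlation. Those higher with magnolol were vitellogenins, oocyte and eggshell markers, germline markers, muscle markers, epidermis and molting markers and the endoplasmic reticulum unfolded protein response, with adjusted p between 1.63e-05 and 0.0401 in camera. With an estimated correlation the adjusted p ran from 0.264 to 0.413. A single member of these lists, mlt-10 (0.65 ± 0.12), was called, and without honokiol 2 it had adjusted p = 0.182 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The yolk protein gene vit-2 stood at 9594 ± 2429.8 CPM with magnolol and 6001 ± 2056 CPM with honokiol, a difference of 0.68 ± 0.21 that was not called. Without honokiol 1 it was 1.06 and called, with adjusted p = 0.0186 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and without the low-count filter that p was 0.0290. By library, vit-2 was at 7800.4, 12359 and 8622 CPM in magnolol 1 to 3 and at 7455 and 4546 CPM in honokiol 1 and 2. The myosin gene unc-54 of the muscle list was likewise highest in magnolol 2 (9142 CPM) and lowest in honokiol 2 (3314 CPM) among the 8 libraries. For the 6 vitellogenins, 6 had an unadjusted p under 0.05, DESeq2 called 0 and limma-voom 0. For the other lists with no call in edgeR, members with an unadjusted p under 0.05 were 4 of 12 oocyte, 3 of 9 germline, 5 of 10 muscle and 3 of 18 endoplasmic reticulum members higher with magnolol, and 10 of 51 sperm markers higher with honokiol. Of these DESeq2 called 1 oocyte and 3 sperm markers, and limma-voom 1 sperm marker. Adjusted over the list alone, 6 vitellogenins, 5 epidermis and 4 muscle markers were higher with magnolol. Those higher with honokiol were glutathione S-transferases, short-chain dehydrogenases, SKN-1 and oxidative stress targets, innate immune effectors, the osmotic response, fat metabolism and fasting, neuropeptides and sperm markers, with adjusted p between 3.58e-05 and 0.00994 in camera and between 0.0988 and 0.345 with an estimated correlation. In the order named, 4, 1, 2, 2, 3, 3, 2 and 0 of their members were called higher with honokiol, or 9, 5, 4, 2, 3, 4, 5 and 1 adjusted over the list alone. These lists share genes, so their counts and tests are not separate. The genes nlp-29 and nlp-31 belong to the innate immune, osmotic and neuropeptide lists. The genes gst-5 and gst-13 belong to both the glutathione S-transferase and the SKN-1 lists. Several of the camera calls between the isomers were lost with 1 library left out. Without honokiol 2, camera gave adjusted p = 0.312 for the oocyte, 0.125 for the germline, 0.212 for the muscle and 0.1005 for the sperm markers, and 0.233 for the endoplasmic reticulum response. The last was also lost without control 1, 2 or 3 (0.0613, 0.0586 and 0.0559) and without magnolol 2 or 3 (0.0735 and 0.0667). Without honokiol 1, camera gave adjusted p = 0.0780 for the osmotic response and 0.0578 for fat metabolism and fasting. Across genes not called between the isomers the log2 differences rose with exon length (Spearman rho = 0.46 over 14590 genes). After correction for that trend camera no longer called the neuropeptides, the germline markers, the muscle markers or the endoplasmic reticulum response, and the sperm markers changed direction at adjusted p = 0.936, while the ABC exporters were called higher with honokiol at adjusted p = 2.10e-05. Ribosomal proteins (7.18e-04), cuticle collagens (4.16e-04), histones (0.0126) and the nuclear-encoded respiratory chain (0.0321) were then called higher with magnolol, these being adjusted p in camera.

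The number of genes higher with magnolol rested on the honokiol libraries: it was 15 without honokiol 2 and 321 without honokiol 1, against 48 with all, 302 in DESeq2 and 90 in limma-voom. It was 81 without control 3, 86 without magnolol 1, 21 without magnolol 2 and 21 without magnolol 3, and the number higher with honokiol was 112 without honokiol 2 against 209.

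The responses to the isomers were alike in direction among called genes. Of the genes called against control, 280 were higher with both compounds, where independent lists would share 11.06, and 24 were lower with both, where independent lists would share 0.46. Both comparisons used the same controls, so the lists are not independent even without a change. Simulated unchanged groups with shared controls gave a mean of 0.01 genes higher and 0.01 lower with both, and at most 1 of each. No gene was called in opposite directions. Of the 280 genes higher with both, 108 were higher with honokiol than with magnolol, 4 were higher with magnolol (cyp-13A8, cyp-13A12, nhr-210 and abt-4, an ABC transporter gene named after its value was seen) and 168 were not called between the isomers. A further 84 genes were called higher with magnolol and not with honokiol, and 16 of them differed between the isomers. Conversely 231 were called higher with honokiol and not with magnolol, and 77 of them differed between the isomers. Across 16813 genes, which are not independent replicates, the log2 changes had Pearson r = 0.664 and Spearman rho = 0.394. Unchanged groups with simulated controls gave a mean r of 0.439, with 0.479 as the highest, and a mean rho of 0.405. Shifts that real libraries share across genes were not simulated, so the spread of r may be larger than simulated. The measured r was 0.505 without honokiol 1 and 0.475 without honokiol 2. The simulation kept every library, so its values are no reference for those fits. The covariance was 0.285 against 0.0525 in the simulation, a difference of 0.233. With 3 control libraries no split leaves 2 controls on each side, so part of the overlap may come from the shared controls.

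**Figure D3:**
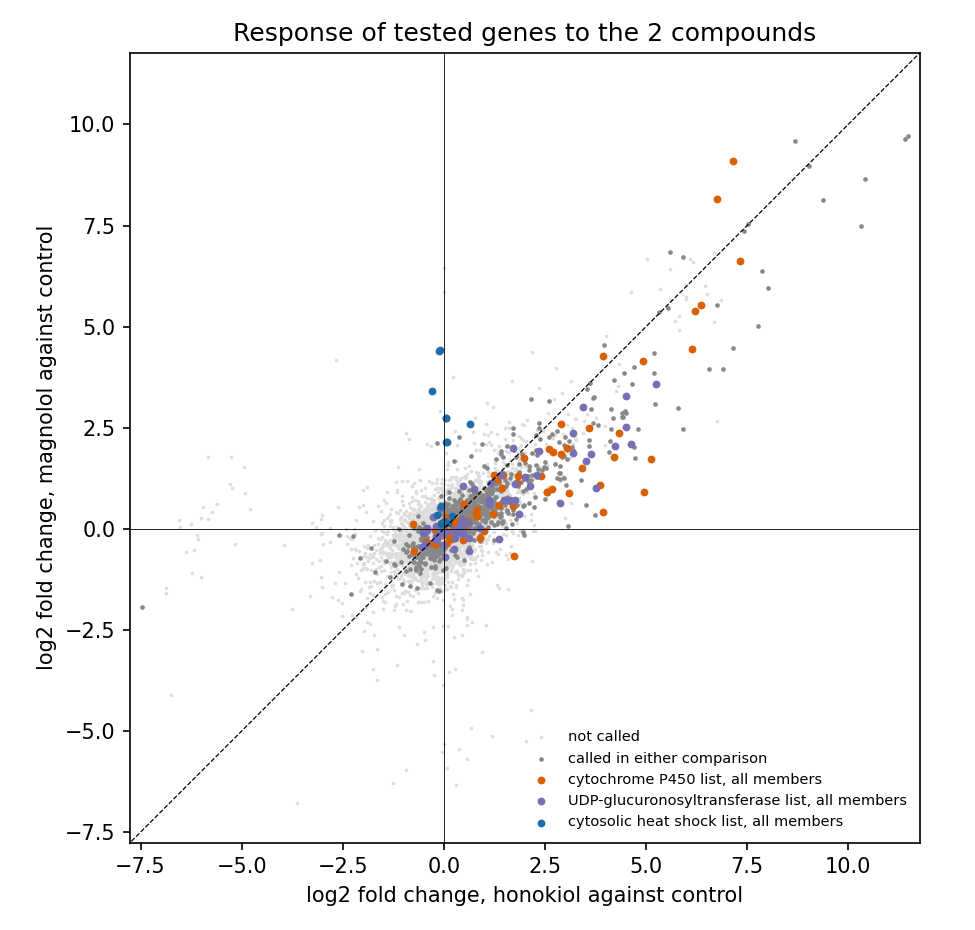
Log2 fold change against control for honokiol (horizontal axis) and magnolol (vertical axis) of each tested gene, with 3 gene lists in colour and the dashed line marking equal change. Of the heat shock rows called with magnolol, hsp-70 lies at -0.30 and hsp-16.41 at 0.65 on the honokiol axis, where neither was called, and most called P450s and UDP-glucuronosyltransferases lie below the line.

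Lists not named above were not called by camera. For magnolol against control these were short-chain dehydrogenases, both the endoplasmic reticulum and the mitochondrial unfolded protein response, hypoxia and hydrogen sulfide response, innate immune effectors, the pals genes of the intracellular pathogen response, C-type lectins, osmotic response, DAF-16 targets, fat metabolism and fasting, phosphatidylcholine synthesis, ribosomal proteins, respiratory chain, proteasome, collagens, histones, chloride channels, vitellogenins, and germline, early zygotic, muscle, intestine, neuron and epidermis markers. Their adjusted p in camera ran from 0.0503 for the hypoxia and hydrogen sulfide response to 0.996. For honokiol the lists not called had adjusted p from 0.0633 for the vitellogenins to 0.993 for the histones in camera, and between the isomers from 0.160 for the cytosolic ribosomal proteins to 0.994 for the DAF-16 targets. The alternative fry called the hypoxia and hydrogen sulfide response, DAF-16 targets and pals genes lower with both compounds. It called the mitochondrial unfolded protein response higher with both, fat metabolism and fasting higher with magnolol, and the osmotic response higher with honokiol. Adjusted p in fry ran from 0.00158 to 0.0287 over these calls. Of 13 mitochondrial unfolded protein response members, 1 was called higher with magnolol and 2 with honokiol. The mean and median log2 change of that list were 0.245 and 0.026 with magnolol, and 0.574 and -0.011 with honokiol. Its call in fry thus does not show a rise across the list. The reporter hsp-6 was not called with magnolol (0.34 ± 0.14) or honokiol (-0.12 ± 0.16). Among lists that were not called, the sign of the median change differed from the direction camera gave for the osmotic response, the respiratory chain, phosphatidylcholine synthesis, C-type lectins and epidermis markers with magnolol. It differed for the mitochondrial unfolded protein response, ribosomal proteins, chloride channels, sperm markers and histones with honokiol, and for the DAF-16 targets and respiratory chain between the isomers. The list of genes encoded in the mitochondrial genome had no row by symbol and was not tested, and hsp-16.2 was not analysed here for the same reason.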

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

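Of the tests in this part, both on gene copies among the heat shock genes (reads shared between copies, and rows of a symbol summed) were chosen only after the result was seen. Every length correction, with all libraries or with 1 left out, was also chosen only then. List tests with a library left out were among the alternatives fixed beforehand. The rule that reads them against a single library was written after the result was seen. By chi-square per degree of freedom, magnolol 2 stood apart from the other magnolol libraries (43.3 and 33.8, against 8.66 between those) and control 3 from the other controls (33.7 and 38.3, against 11.9), while 2 honokiol libraries cannot show which stands apart. For magnolol against control, 288 genes were called higher and 53 lower without magnolol 2, and 376 and 90 without control 3. Between the isomers 21 were higher with magnolol and 160 with honokiol without magnolol 2, and 81 and 249 without control 3. What set these libraries apart was not tested.

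The isomers differed by the test of the difference itself for several lists. The median log2 difference, magnolol minus honokiol, was 1.94 for the cytosolic heat shock list, -0.41 for cytochrome P450s, -0.42 for UDP-glucuronosyltransferases, -0.36 for the metal response and -0.20 for nuclear hormone receptors. Among 280 genes raised by both compounds, the log2 difference was 1.94 for cyp-13A8, 1.40 for cyp-13A12, 1.04 for nhr-210 and 0.77 for abt-4.

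For the heat shock genes, with a median difference of 2.69 over the 8 called rows, the whole cytosolic heat shock list stayed higher with magnolol with any library left out, at a highest adjusted p of 1.44e-27 in camera, which argues against a single library. The median was also 2.69 after the length correction, but it rested on the 2 rows of hsp-16.1 (2.68 and 2.69). Rows without an exon length were left uncorrected, so a median that did not move cannot decide on a length trend. Reads divided between rows of one symbol cannot be told apart from separate changes, since each row of hsp-16.1, hsp-16.48 and F44E5.4 was called by itself and a sum that left 3 of 3 symbols called decides nothing. Reads shared between near-identical gene copies of different symbols cannot be told apart from them either, with 2 called members, hsp-70 and hsp-16.41, on rows of their own. The number of genes involved and what produced the pattern stay open, a difference between the compounds included.

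For the 43 P450 and UDP-glucuronosyltransferase genes called higher with honokiol, the median difference was -1.11. Tested as whole lists, both stayed higher with honokiol with any library left out, at a highest adjusted p of 1.55e-25 in camera, which argues against a single library. After the length correction the median was -1.16, which argues against a length trend as the whole cause. Reads shared between paralogs were not tested for these genes. What produced the pattern stays open, a difference between the compounds included.

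The number of genes called higher with magnolol than with honokiol was 48 with all libraries and 321 without honokiol 1, or 38 and 103 after the length correction. The log2 ratio of honokiol 2 to honokiol 1 followed exon length across 14823 genes (Spearman rho = -0.29), which are not independent replicates, and for the other pairs within a group rho was 0.44 for magnolol 2 to 1, -0.33 for magnolol 3 to 2, 0.23 for magnolol 3 to 1, -0.21 for control 3 to 1, -0.17 for control 3 to 2 and -0.05 for control 2 to 1. A transcript length trend between libraries is a candidate explanation for this dependence, and what produced the trend was not tested. Whether it was the whole cause or part of it stays open, since the corrected count still rose 2.71-fold without honokiol 1, but leaving out a control or magnolol library moved it by up to 2.21-fold, and 2 SD of those moves is 2.86-fold.

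Magnolol and control, fitted alone, gave 498 called genes, and the highest of the other splits of these 6 libraries gave 1. The real split was thus 1 of 10 splits with as many genes, and 10 splits are too few for a share under 0.05.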

How the results depend on the processing

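Fits without the added loci, with rows of a symbol summed and with the length correction were chosen after the data were seen. Over the alternatives fixed beforehand the calls of named genes stayed the same in 4294 cases, became stronger in 107 and weaker in 138, and none reversed. The 43 list tests called by camera stayed the same in 400 cases and weakened in 73, with the estimated correlation, fry, the replicate block or a library left out. Lists not called at first became called in 25 of 715 such cases, 10 of them with fry. Under the added alternatives named genes stayed the same in 779, strengthened in 5 and weakened in 4, and the called lists stayed the same in 78 and weakened in 7. The length correction newly called 6 lists. The sperm markers between the isomers reversed with the length correction, at adjusted p = 0.936 in camera. Depth was not varied, and cyp-13A8 had 23 counts over the 3 control libraries. Counts of genes moved as follows. A stricter threshold or a 2-fold minimum lowers a count by construction, and the cause of the other moves was not tested. Leaving out a library raised some counts and lowered others, so fewer libraries alone do not give these moves. For magnolol, the count of higher genes was 181 at 2-fold, and that of lower genes was 183 without the low-count filter, 236 in DESeq2, 37 at an adjusted p under 0.01, 13 at 2-fold and 36 to 135 with a library left out. For honokiol, higher genes numbered 298 at 2-fold, and lower genes 116 in DESeq2, 17 at 0.01, 16 at 2-fold and 35 to 74 with a library left out. Between the isomers, genes higher with magnolol numbered 261 without the filter, 302 in DESeq2, 90 in limma-voom, 18 at 0.01, 17 at 2-fold and 15 to 321 with a library left out, and genes higher with honokiol 315 without the filter, 98 at 2-fold and 112 to 253 with a library left out. The correlation of the responses was 0.543 without the filter, 0.881 over called genes and 0.475 to 0.757 with a library left out. With the replicate number as a block, the counts were 283 higher and 60 lower for magnolol, 420 and 33 for honokiol, and 16 higher with magnolol and 147 higher with honokiol. Deviations of same-numbered libraries correlated at -0.21, -0.12 and -0.12 for magnolol and control. They correlated at 0.18 and 0.19 for honokiol and control, and at -0.42 and -0.53 for the isomers. No library correlated best with its own number, so no pairing by number was seen. The library names of the honokiol group skip a number, so its numbers may not match those of the other groups. Whether the replicates were paired stays open.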

Other observations

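The test of symbol families was chosen only after the calls were seen.

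Families sharing a symbol prefix were tested with Fisher's exact test, one-sided, with Benjamini-Hochberg adjustment over 368 families. With honokiol 7 of 31 carboxylesterase-family cest genes rose (adjusted p = 0.00640) and 4 of 9 fatty acid elongase genes (adjusted p = 0.0103). With magnolol 5 of the cest genes rose, which did not pass (adjusted p = 0.0639). Between the isomers 5 cest genes (adjusted p = 0.0115) and 3 elongase genes (adjusted p = 0.0250) were higher with honokiol. The genes cest-35.2, named after its value was seen, and cest-33 changed by 2.48 ± 0.22 and 0.74 ± 0.10 with magnolol and by 4.81 ± 0.23 and 2.51 ± 0.11 with honokiol. P-glycoprotein genes of the pgp family rose in 5 of 14 with each compound (adjusted p = 0.00147 with magnolol and 0.00640 with honokiol). Fisher's test takes genes as independent, which members of a family may not be, so these p-values may be too small. The ABC exporter list, which holds the pgp genes, was not called by camera with an estimated correlation (adjusted p = 0.228 with magnolol and 0.317 with honokiol).

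C06E4.6 and C06E4.3, neighbours on chromosome IV of WBcel235 (7257100 to 7258303 and 7260875 to 7262138), had large rises with both compounds. C06E4.6 rose by 8.14 ± 0.30 with magnolol and 9.37 ± 0.30 with honokiol, and C06E4.3 by 5.55 ± 0.18 and 6.75 ± 0.18. C06E4.6 was at only 0.175, 0 and 0.066 CPM in controls 1 to 3, so the size of its rise is uncertain.

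Of 252 genes raised by both compounds with a position, 34.1% had another within 10 kb, against a median of 7.54% and an upper 95% limit of 12.302% in 10000 random sets matched on expression (permutation p = 0.0001, the smallest these draws can give). Among neighbours of another symbol prefix the share was 11.51%, against a median of 6.35% and an upper limit of 10.7% (permutation p = 0.0130). Pairs with the same prefix may account for much of the excess, and the share left outside them passed the limit narrowly. Genes named by a shared clone, such as C06E4.6 and C06E4.3, counted as the same prefix whether related or not. The fall in the share thus does not measure families alone. Relatives with different symbols counted as another prefix. How much of the excess comes from families, and whether they are the whole cause, stays open.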
